A study of Rattus norvegicus with 4 samples.

How the data were processed

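Gene expression was measured in primary neurons from the cortex of rat embryos at day 17, kept for 14 days in serum-free neuronal medium. The cultures then received phosphate-buffered saline (control) or 25 mM KCl, which depolarizes the cell membrane, for 4 h. There were 4 hybridizations, 2 per group, named here control 1, control 2, KCl 1 and KCl 2 after their titles. The groups come from the titles and the treatment protocols, which match each other. The description label gives all 4 samples, KCl included, the same wording of an unstimulated state, so the labels are in conflict there. Nothing in the labels says whether the 2 samples of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

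Per the labels' protocols, biotin-labelled cRNA was made from 5 µg of total RNA and hybridized to Affymetrix arrays made for neurobiology, which are 1-colour arrays. The deposited values are probe set intensities on a linear scale, in arbitrary units. The algorithm that combined the probes of a set, its software and its scaling target are not given in the sources used here. The values themselves show that the arrays had already been brought to one level, because their 2% trimmed means lay between 502.0 and 502.4 and their median log2 intensities within 0.13 of each other. They were therefore used as deposited and taken to log2. All values were above 0, so no floor was set.

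The table held 1322 probe sets. The 59 Affymetrix control probe sets were left out of the test and used for quality. Of the other 1263, the platform annotation gave 1 gene symbol to 1137, several to 8 and none to 118. Every symbol used came from this annotation, and probe sets without a symbol are given by their identifier. No chromosome positions are given, since the array has no genome build of its own. The dimmest 25% of probe sets by mean intensity over the 4 arrays (316 probe sets, means up to 33.3) were left out, which left 947 to be tested, 853 of them with 1 symbol and together covering 570 genes. Background was read from 19 probe sets for bacterial and yeast transcripts, whose median intensity was 9.05 and whose highest was 73.7. A group whose values all lay at or below 73.7 is called within background, and a fold change against it depends on that background.

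KCl was compared with control by limma (version 3.58.1 in R 4.3.3), with lmFit and with eBayes set to let the prior variance follow the mean intensity. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over the 947 probe sets, and a probe set is called higher or lower at an adjusted p below 0.05. Fold changes are ratios of geometric means, errors of log2 changes are limma's moderated standard errors (SE), and intensities are given as mean ± SD of the 2 arrays of a group. With 2 arrays per group an exact permutation test could not give a two-sided p below 0.33, so the calls rest on variances shared across probe sets. The number of arrays limits the precision. The median SE of a log2 change was 0.21 and the smallest log2 change called was 0.40.

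A total of 26 gene lists for neuronal functions, stress and cell types was fixed before the data were examined, as were the model, its filters and the alternatives, apart from the counts of list members without each array, which were added later. Each gene entered through its probe set with the highest mean intensity, and other probe sets are mentioned where their call differs or, for genes whose log2 change is given, its direction. The 21 lists with at least 5 tested genes were tested with limma's camera, with a preset correlation between genes of 0.01 and adjustment over the 21 lists, and again with the correlation estimated from the arrays. Members were counted after adjustment over all probe sets and also adjusted over the list alone.

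The genes named were chosen by a rule fixed with the lists. It took the 15 largest rises and 10 largest falls among genes that passed and whose KCl arrays both lay on one side of both control arrays, a set of genes known for activity-dependent or synaptic roles, and the 4 members of each list with the smallest p. Of that set, Arc, Homer1, Scg2, Inhba, Gad2, Gfap, Actb and Gapdh had no tested probe set with their symbol. Some of them may still have been measured, since 118 probe sets had no symbol and were not matched to genes. Other genes that are named were chosen after their values were seen.

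The alternatives were quantile normalization, scaling to 1 trimmed mean, centring on the median, a pseudocount, no filter or a stricter filter on dim probe sets, a replicate block, leaving out each array in turn, eBayes without the intensity trend, an ordinary t statistic, 1 probe set per gene, other thresholds, and for the lists an estimated correlation, limma's fry and means over the probe sets of a gene. The test was checked on simulated arrays in which 200 of 947 probe sets were changed. They had the real mean of each probe set, limma's moderated variance and independent normal noise. The simulation thus takes the variance model as true and cannot check it. It recovered 46.3% of changes of 0.5 in log2, 74.6% of changes of 1 and 93.9% of changes of 2, and 4.67% of its calls were false. In 20 simulated sets with no change it made 14 calls in all, at most 4 in a set. Camera with the preset correlation called 3 lists in another 20 sets with no change. A list of 11 genes shifted by 1 in log2 had a camera adjusted p of 3.6e-30 with the preset correlation and 0.12 with an estimated one, so the latter missed this shift. The simulated genes varied independently of each other, which favours the preset value. In the real data the estimated correlation was 0.10 for the activity-regulated transcription factors, 0.50 for the effector genes and 0.13 for the astrocyte markers. The simulation therefore cannot tell which of the 2 settings is right for the real lists. The plots were drawn with matplotlib 3.10.9.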

Results

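Transcript levels in cultured rat cortical neurons were compared between 2 arrays of control cultures given saline and 2 arrays of cultures held for 4 h in 25 mM KCl. Raised extracellular potassium depolarizes neurons and opens their voltage-gated calcium channels, and the comparison asks which genes respond to this. Across the 947 probe sets tested, log2 intensities of the control pair had a Pearson r of 0.97 and differed with an SD of 0.54, and those of the KCl pair had an r of 0.97 and an SD of 0.55. Between a control and a KCl array, r lay between 0.93 and 0.94 and the SD between 0.76 and 0.83. Probe sets are not independent replicates, so these values carry no p. The 3′ to 5′ signal ratio of the Gapdh control probe sets, a measure of RNA integrity, lay between 1.17 and 1.23 on the 4 arrays. That of the β-actin control probe sets lay between 1.08 and 1.12, and neither separated the groups. That of the hexokinase control probe sets was 2.25 and 2.00 on the control arrays and 2.49 and 2.67 on the KCl arrays.

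After KCl, Fos, Nr4a1 and Junb, immediate-early genes that encode transcription factors, showed the largest rises. The largest falls were in Nxph1, in Gad1, Slc32a1 and Sst, genes that inhibitory neurons use, and in the potassium channel gene Kcnc2, whose KCl values lay within background so that its fold is imprecise. Fos rose 14.4-fold, from an intensity of 683 ± 52 to 9814 ± 98 (SD, n = 2 arrays per group), with a log2 change of 3.85 ± 0.11 (SE; limma adjusted p = 9.2e-08). Nr4a1 rose 9.90-fold, from 274 ± 20 to 2710 ± 144, and Junb 7.97-fold, from 487 ± 12 to 3881 ± 79. Bdnf, which encodes brain-derived neurotrophic factor, rose 5.84-fold, from 187 ± 36 to 1081 ± 71. Gad1, which encodes an enzyme of GABA synthesis, fell 3.45-fold, from 1024 ± 131 to 299 ± 65, and Sst, which encodes the neuropeptide somatostatin, fell 2.92-fold, from 5345 ± 207 to 1832 ± 168.

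**Figure D1:**
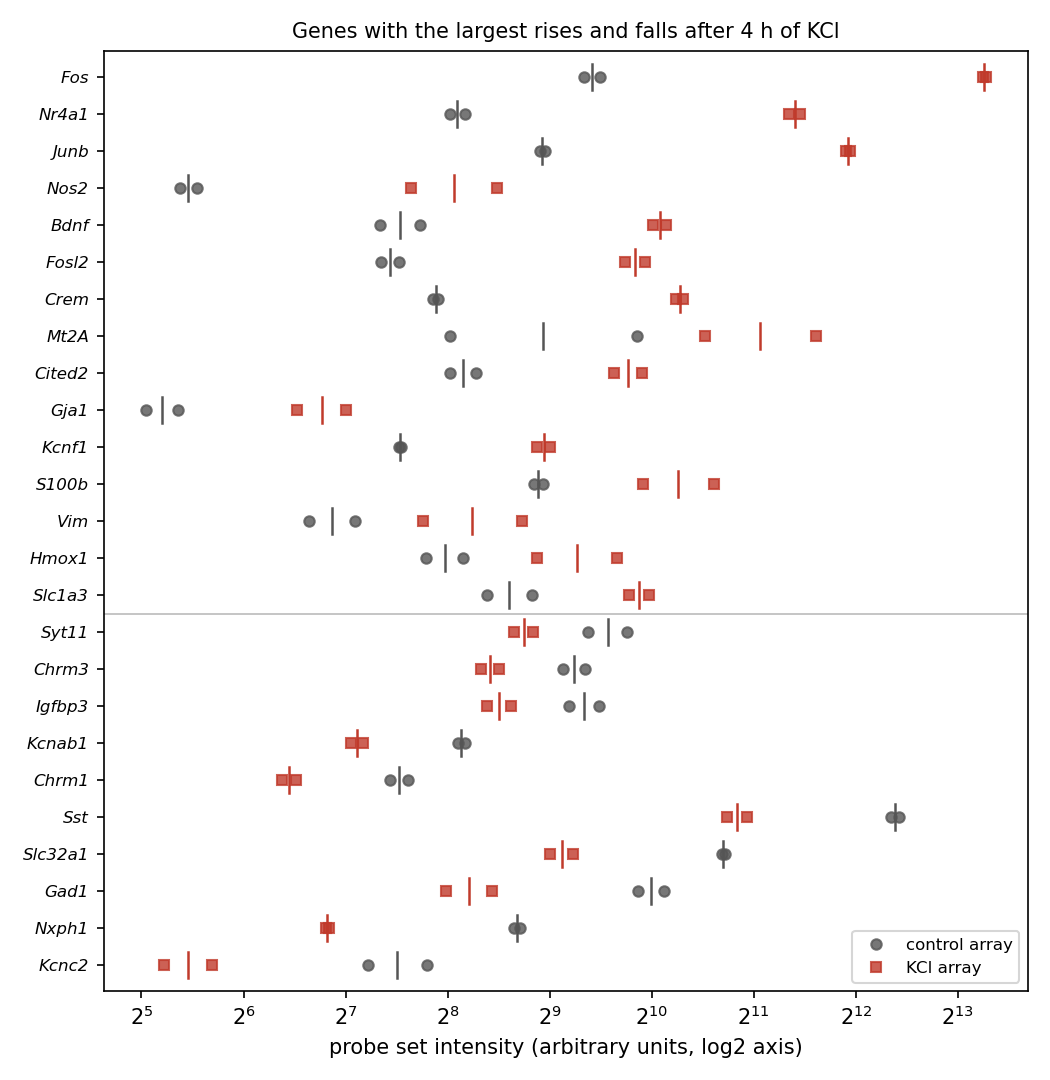
Intensity of the 15 genes with the largest rises and the 10 with the largest falls on each array, on a log2 axis in arbitrary units. Grey circles are the 2 control arrays, red squares the 2 KCl arrays, and vertical bars the geometric mean of each group. The 2 KCl arrays of each gene lie on one side of its 2 control arrays, with Fos at 9744 and 9883 after KCl against 720 and 646 in controls.

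In all, 102 of 947 probe sets (10.8%) changed, 52 higher and 50 lower after KCl, and 242 had an unadjusted p below 0.05. The probe sets with a symbol named 30 genes that rose and 39 that fell, and no gene had probe sets called in both directions. A gene is counted here if any of its probe sets passed. Of 41 genes with several tested probe sets and a changed one, 30 also had one that did not pass, and 20 had 2 or more that changed. The rises were larger: 40 of the 52 reached 2-fold and 14 reached 4-fold, against 13 and 2 of the 50 falls. The 4 intensities of all 102 changed probe sets separated the groups, as did those of 549 of the 947 tested (58.0%), where chance gives 33.3%. The counts changed when 1 array was left out, where the spread of a probe set comes from the 2 arrays of the other group alone. Fewer probe sets were called when the KCl pair gave the spread (without control 1 or without control 2), and more when the control pair did. Calls given below without a control array thus rest on the spread of the KCl pair. With each array left out in turn, the log2 change of Slc32a1 ran from −1.69 to −1.47 and that of Mt2A from 1.21 to 3.04. The counts also depended on the variance model, with 21 called when the intensity trend was left out (18 higher and 3 lower). With an ordinary t statistic 0 were called, and 157 probe sets had an unadjusted p below 0.05. Of the genes in the lists below, those that passed without the trend were Fos, Nr4a1, Junb, Fosl2, Crem, Bdnf, Kcnf1, Sst and Slc32a1. The falls numbered 32 with quantile normalization and 33 without the filter on dim probe sets, beside 48 and 46 rises.

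Of the activity-regulated transcription factors, genes long known to respond to neuronal activity, all 10 tested rose and none fell (camera adjusted p = 1.7e-18; adjusted p = 0.40 with an estimated correlation). The count was also 10 when adjusted over the list alone. Beyond Fos, Nr4a1 and Junb, the list held Fosl2, a partner of the Jun proteins in the AP-1 complex, which rose 5.27-fold, and Crem, a relative of the cAMP-responsive factor CREB, which rose 5.26-fold. Cebpb rose 2.24-fold, Nr4a3 2.14-fold, Jund 2.07-fold and Jun 1.79-fold. Egr1, a zinc-finger immediate-early gene, rose 1.72-fold from a high control level of 4008 ± 234 to 6923 ± 868, and 3 of its 4 probe sets passed. All 3 probe sets of Fos rose, with log2 changes of 3.85 to 4.53. Without control 1, 6 of the 10 genes passed, and without control 2, 5 did, which were Fos, Nr4a1, Junb, Fosl2 and Crem. The astrocyte markers described below rose on the same arrays, with a mean log2 change of 1.13 against 1.99 for this list.

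Among the activity-regulated effector genes, 3 of 8 rose and none fell (camera adjusted p = 0.00047; adjusted p = 0.79 with an estimated correlation and 0.11 with fry), and adjusted over the list alone 3 rose as well. They were Bdnf, Vgf, whose product is a precursor of secreted peptides, at 2.32-fold, and Dusp5, which encodes a phosphatase of MAP kinases, at 2.08-fold. Of the 7 probe sets of Bdnf, 5 rose, with log2 changes up to 2.84, and 2 did not pass, with 0.17 and −0.07. The 5 members that did not pass included Ptgs2, the inducible cyclooxygenase, with a log2 change of 0.40 ± 0.31, the neuronal pentraxin gene Nptx2 with −0.09 ± 0.20 on its brightest probe set and 0.94 ± 0.29 on the other, and Plat, tissue plasminogen activator, whose values lay within background in both groups. A less bright probe set of Syt4, another of the 5, was higher. Without control 1 or without control 2, 1 member passed, Bdnf. The astrocyte markers rose on the same arrays by a mean of 1.13 in log2, against 0.87 for this list. Vgf was also the 1 tested gene of the list for peptide processing and dense-core vesicles.

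Most astrocyte markers rose after KCl. Of 7 tested, 6 rose and none fell (camera adjusted p = 3.3e-06; adjusted p = 0.60 with an estimated correlation and 0.074 with fry), and the count was again 6 when adjusted over the list alone. Apoe, the main apolipoprotein of the brain, rose 2.41-fold, from 2499 ± 285 to 6061 ± 1223. The glutamate transporter gene Slc1a3 rose 2.41-fold, from 394 ± 85 to 940 ± 90. S100b, which encodes a calcium-binding protein of astrocytes, rose 2.59-fold and Vim, which encodes the intermediate filament vimentin, 2.59-fold. Gja1, the gene of the gap junction protein connexin 43, rose 2.96-fold from control values within background. Glul, which encodes glutamine synthetase, rose 1.41-fold, and Slc1a2, with all values within background, did not pass. The call held for 1 of 2 probe sets of S100b, 2 of 4 of Slc1a3 and 2 of 4 of Glul. The KCl arrays differed for some of these genes, with Vim at 423 on KCl 1 and 216 on KCl 2 and S100b at 1558 and 966. Of the 7 markers, 5 were higher on KCl 1 than on KCl 2. Their median ratio of KCl 1 to KCl 2 was 1.33, against 0.95 over all 570 genes and 1.00 for the neuron markers. The median ratio of control 1 to control 2 for the astrocyte markers was 0.94. Without control 1, and likewise without control 2, 0 of the 7 passed, and without KCl 1 4 did, Gja1 and Vim being lost. With quantile normalization and with dim probe sets kept 4 passed, and with the arrays centred on the median 3 (Apoe, S100b and Slc1a3), while without the intensity trend 0 did.

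The neuron and oligodendrocyte marker lists did not pass. Of 12 neuron markers, Snap25, which encodes a protein of synaptic vesicle fusion, rose 1.35-fold on 1 of its 4 probe sets, and the other 11 genes did not pass, among them Map2 with a log2 change of −0.11 ± 0.11 (its other 4 probe sets −0.05 to 0.68) and Gap43 with −0.16 ± 0.11 (list mean 0.03; camera adjusted p = 0.68). Snap25 did not pass in 7 of 14 alternatives, among them those without control 1, without control 2, with the arrays centred on the median, with dim probe sets kept and without the intensity trend. With quantile normalization Syp, the synaptophysin gene, fell (log2 change −0.29 ± 0.10 as deposited, not passing). None of the 5 oligodendrocyte lineage markers passed in limma and 0 had an unadjusted p below 0.05, by limma or by an ordinary t statistic (camera adjusted p = 0.87, upward, with a median of −0.33 and a mean of −0.03). Of these, Cnp and Mag lay above background, with log2 changes of −0.36 ± 0.21 and 0.23 ± 0.18, and the other probe set of Mag had −0.26 ± 0.21. Of the microglial and immune markers 2 were tested, Ccl2 and Itgam, both within background, and 0 had an unadjusted p below 0.05. Of the endothelial and fibroblast markers 2 were tested, and neither passed in limma, although Vcam1 had an unadjusted p of 0.026 (log2 change 0.72 ± 0.27).

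In the heat shock and oxidative stress list, 3 of 10 genes rose and none fell, also when adjusted over the list alone, and the list as such did not pass (camera adjusted p = 0.051), although it did without KCl 1 (adjusted p = 0.026) and without KCl 2 (adjusted p = 0.0027). Without control 1 and control 2 in turn its adjusted p was 0.31 and 0.12, and with an estimated correlation 0.79. Nos2, the inducible nitric oxide synthase gene, rose 6.07-fold on 1 of its 5 probe sets, from control values within background, and the other 4, with log2 changes of −0.78 to 0.37, did not pass. The metallothionein gene Mt2A rose 4.36-fold, with unlike replicates of 924 and 261 in controls and 3116 and 1468 after KCl. Hmox1, which encodes the haem-degrading enzyme heme oxygenase 1, rose 2.46-fold and reached 810 on KCl 1 and 471 on KCl 2. The astrocyte markers rose beside these genes, by a mean of 1.13 in log2. None of the 3 passed without control 1 or without control 2, and without KCl 2 Mt3 passed as well. Mt2A also did not pass with quantile normalization, with the arrays centred on the median or with dim probe sets kept.

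Several genes that inhibitory neurons use fell. In the list for GABA synthesis and transport, too short for a list test, 2 of 4 tested genes fell and none rose, also when adjusted over the list alone. They were Gad1 (log2 change −1.79 ± 0.18; limma adjusted p = 0.00048) and Slc32a1, the vesicular GABA transporter gene, which fell 2.99-fold, from 1665 ± 26 to 558 ± 61, on 1 of its 2 probe sets. Abat, which encodes the GABA-degrading transaminase, and the GABA transporter gene Slc6a11 did not pass, with log2 changes of −0.15 ± 0.22 and −0.01 ± 0.19. Sst was the only 1 of 12 neuropeptide genes that passed, on both of its probe sets (list camera adjusted p = 0.68; 1 fell when adjusted over the list alone). Npy, with 600 ± 3 in controls and 709 ± 135 after KCl, and Penk did not pass. Nxph1, which encodes the neurexin ligand neurexophilin 1, fell 3.63-fold, from 411 ± 12 to 113 ± 1. Without control 1 or without control 2, Gad1, Slc32a1 and Nxph1 did not pass, and Sst did. These falls stood beside the rise of the astrocyte markers (mean log2 change 1.13) and the unlike hexokinase 3′ to 5′ ratios of the groups (2.25 and 2.00 in controls, 2.49 and 2.67 after KCl). The ratios of Gapdh (1.17 to 1.23) and β-actin (1.08 to 1.12) did not separate the groups.

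**Figure D2:**
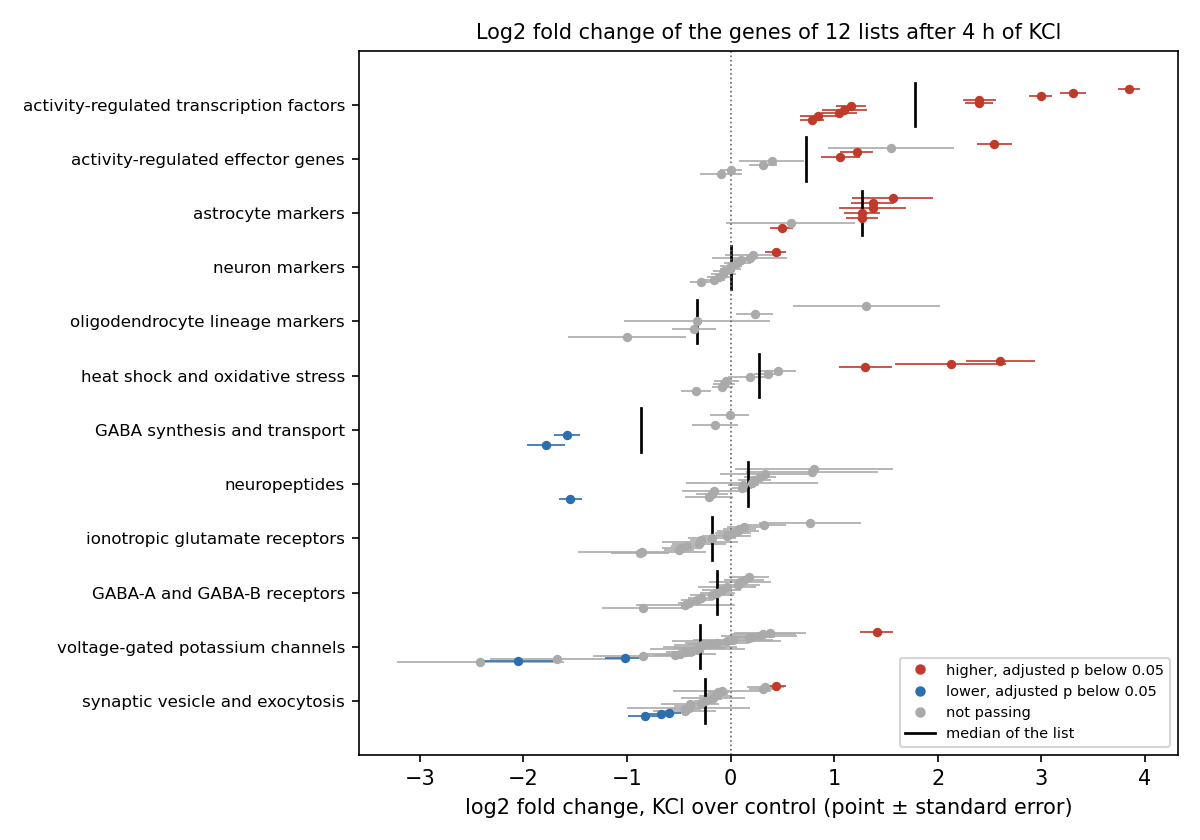
Log2 fold change of KCl over control for each tested gene of 12 gene lists, with horizontal bars for the standard error and a black vertical bar for the list's median. Red points rose, blue points fell and grey points did not pass. All 10 activity-regulated transcription factors and 6 of 7 astrocyte markers lie among the rises, while 11 of 12 neuron markers did not pass.

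Among ion channels, the voltage-gated potassium channel list had 1 rise and 2 falls in 23 genes (camera adjusted p = 0.68), and 1 and 3 when adjusted over the list alone. Kcnf1, which encodes a modulatory subunit, rose 2.65-fold, from 185 ± 2 to 492 ± 31. Kcnc2, which encodes a Kv3 channel of fast-spiking neurons, fell 4.16-fold into background, from 186 ± 52 to 44 ± 10, on 1 of its 2 probe sets, and Kcnab1, which encodes an auxiliary subunit, fell 2.03-fold. None of these passed without control 1 or without control 2, and the falls numbered 4 without KCl 1 and 4 without KCl 2. In limma no gene passed among 13 other potassium channel genes, 9 sodium channel genes and 11 calcium channel genes, where 5, 1 and 3 had an unadjusted p below 0.05 (2, 0 and 1 by an ordinary t statistic), and adjusted over the list alone none passed either. Camera adjusted p-values of these lists were 0.68, 0.68 and 0.67. Without KCl 1 the sodium channel gene Scn4a passed as lower. The calcium channel gene Cacna1c and Kcnmb1 passed as lower without KCl 2, and Scn3a as higher.

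Few receptor genes passed. None of 17 ionotropic glutamate receptor genes passed in limma, while 5 had an unadjusted p below 0.05, all lower after KCl, and 1 by an ordinary t statistic (camera adjusted p = 0.68). The AMPA receptor genes Gria1 and Gria2 had log2 changes of −0.50 ± 0.15 (adjusted p = 0.071) and −0.42 ± 0.15 (adjusted p = 0.13), and the NMDA receptor genes Grin1, Grin2a and Grin2b had 0.13 ± 0.16, 0.33 ± 0.21 and 0.08 ± 0.16. Other probe sets of Grin1 had −0.61 ± 0.19 (adjusted p = 0.080) and −0.41 ± 0.66, and those of Gria1 −0.49 ± 0.19 and 0.16 ± 0.48. None of 6 metabotropic glutamate receptor genes and none of 13 GABA receptor genes passed in limma, with 1 unadjusted p below 0.05 in each by limma and 1 by an ordinary t statistic, and the camera adjusted p was 0.68 for both lists. Less bright probe sets of Grm7 and Gabra5 were lower. Adjusted over the list alone, none of these 3 lists had a gene that passed. Of 32 monoamine and acetylcholine receptor genes, Chrm1 and Chrm3, which encode the M1 and M3 muscarinic receptors, fell 2.10-fold and 1.77-fold, each on 1 of 2 probe sets, and 30 did not pass (camera adjusted p = 0.87; 2 fell when adjusted over the list alone). Without control 1 or without control 2 neither muscarinic gene passed. Gria1 passed as lower and Grik3 as higher without KCl 1, and Gria2, Grm7, Gabbr2 and Drd1 passed as lower without KCl 2. Gabbr2 also passed with a pseudocount and with the stricter filter on dim probe sets.

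Genes of glutamate handling moved both ways. In a list of 6, which shares Slc1a3 and Glul with the astrocyte markers, these 2 rose, and Slc1a1, a neuronal glutamate transporter gene, fell 1.36-fold, from 1717 ± 60 to 1262 ± 70, with 2 of its 3 probe sets passing (camera adjusted p = 0.68). Adjusted over the list alone, 2 rose and 2 fell, the second being Slc1a6. Of 16 neurotrophic factor and receptor genes, Bdnf rose and Ntf3, which encodes neurotrophin 3, fell 1.64-fold, from 525 ± 63 to 320 ± 23, on 1 of its 2 probe sets. Camera's direction for this list was upward (adjusted p = 0.68) and its median and mean log2 changes were −0.03 and −0.03, and adjusted over the list alone 1 rose and 1 fell. Without control 1 or without control 2, Bdnf was the 1 gene of these that passed. Slc1a1 did not pass with dim probe sets kept or without KCl 1, when Glud1 fell instead, and Tgfa fell too without KCl 2.

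In the synaptic vesicle and exocytosis list, 1 of 19 genes rose, Snap25 on 1 of 4 probe sets, and 3 fell, also when adjusted over the list alone (camera adjusted p = 0.21). Syt11, which encodes a synaptotagmin, fell 1.77-fold, Sncb, the β-synuclein gene, 1.60-fold and Nrxn2, which encodes a presynaptic adhesion protein, 1.51-fold on 1 of its 2 probe sets, the other having a log2 change of −0.07. A less bright probe set of Syt4 was higher. Of 18 genes of the postsynaptic scaffold and of calmodulin-dependent signalling none passed in limma, nor adjusted over the list alone, while 4 had an unadjusted p below 0.05 and 7 by an ordinary t statistic (camera adjusted p = 0.21; adjusted p = 0.050 with fry, just under the threshold). In the protein kinase list of 14, Crem rose and Mapk14, which encodes the p38α kinase, fell 1.51-fold, with 2 of its 6 probe sets passing (camera adjusted p = 0.68, downward, with a median of −0.19 and a mean of 0.10; 1 rose and 2 fell when adjusted over the list alone). Less bright probe sets of Mapk9, Prkcb and Prkcz were lower. None of 11 cell death genes passed in limma, nor adjusted over the list alone, with 1 unadjusted p below 0.05 by limma and 1 by an ordinary t statistic (camera adjusted p = 0.95, upward, with a median of −0.11 and a mean of 0.01), although less bright probe sets of Bcl2l1 and Bax were lower. In these 4 lists only Crem passed without control 1 or without control 2, and Mapk14 did not pass without KCl 1. Leaving out KCl 2 added falls of Syn2 and Syt3 in the synaptic vesicle list, Dlg3 and Nlgn3 in the postsynaptic list and Prkar2b in the kinase list. Among the cell death genes Casp2 then passed as lower and Tnfrsf1a as higher. With quantile normalization neither Mapk14 nor Syt11 passed while Syp fell, so the synaptic vesicle list again had 3 falls. With dim probe sets kept Mapk14 and Snap25 did not pass, and with the stricter filter Mapk9 passed in addition.

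Of 3 reference genes tested, B2m, which encodes the β2-microglobulin of MHC class I, rose 2.38-fold, from 185 ± 51 to 432 ± 54, also when adjusted over the list alone. Tubb5 and the transferrin receptor gene Tfrc did not pass, with log2 changes of −0.21 ± 0.14 and −0.01 ± 0.22. B2m did not pass without control 1 or without control 2. Cited2, which encodes a regulator of CBP and p300 and belongs to none of the lists, rose 3.06-fold, from 285 ± 35 to 875 ± 116, and Igfbp3, which encodes a binding protein of insulin-like growth factors, fell 1.78-fold, from 651 ± 92 to 365 ± 41. Neither passed without control 1 or without control 2.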

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

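All settings but the list counts without each array were chosen before the data were examined. Under them no result changed direction among the 38 named genes called. For most settings this was fixed in advance. The replicate block, the variance models, the filters and 1 probe set per gene leave a log2 change as it is. The groups lay apart for all 102 changed probe sets, so leaving out 1 array or adding a pseudocount cannot reverse it. Only the settings that rescale the arrays could have done so. The counts of 102 changed, 52 higher and 50 lower stayed within 1.5 times with scaling to 1 trimmed mean, median centring, a pseudocount and the dimmer part left out. With quantile normalization 32 were lower, without the filter on dim probe sets 33, and at an adjusted p below 0.10 82, the last because the threshold was wider. Without the intensity trend 21 passed, 18 higher and 3 lower, and with an ordinary t statistic 0, with 0 higher and 0 lower, although 157 had an unadjusted p below 0.05. With 1 probe set per gene, which tests fewer, 58 passed, 29 higher and 29 lower, and 46 (31 and 15) differed at least 2-fold in all 4 pairings of the arrays. With the replicate number as a replicate block 50 passed, 35 higher and 15 lower. Of the 38 genes, 15 then did not pass, among them Gja1, Vim, Glul, Hmox1, Jun, Dusp5, Kcnc2, Kcnab1, Chrm1 and Chrm3. With the block 3 of 7 astrocyte markers rose, and 0 voltage-gated potassium channel genes and 0 monoamine and acetylcholine receptor genes fell. The labels do not say that the replicate numbers pair the arrays, and same-numbered deviations from the group means had a correlation of −0.03. Leaving out 1 array gave 11 (without control 2) to 178 (without KCl 2) calls, 10 to 72 higher and 1 to 106 lower, with 14 calls without control 1 and 105 without KCl 1. The lone array of a group is there assumed to vary like the other group. Of the 38 genes, 31 did not pass without control 1, the same 31 without control 2, and 27 without the trend, while Fos, Nr4a1, Junb, Bdnf, Fosl2, Crem and Sst passed in every setting except the ordinary t statistic. The 3 list calls became 0 with an estimated correlation, when 1 list had an unadjusted p below 0.05, and were 3 to 4 with 1 array left out. The heat shock and oxidative stress list passed without KCl 1, without KCl 2 and with the replicate block (adjusted p = 0.020). With fry, which does not compare a list with other genes, the effector and astrocyte lists did not pass and the postsynaptic list did (adjusted p = 0.0499). The SD between replicates was 0.71 (control) and 0.66 (KCl) with dim probe sets kept and 0.30 and 0.34 with the dimmer part left out. Except where stated, the cause was not tested. Signal over background limits the dim genes, since 120 tested probe sets lay within background on all 4 arrays.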

Other observations

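The tests in this part were all chosen after the results were seen, and so were the genes it names that the report does not. Outside the gene lists, 20 genes passed, 4 higher and 16 lower. Besides Cited2, the rises were Gsta1, a glutathione S-transferase gene, at 2.09-fold, Bcan, which encodes the brain matrix proteoglycan brevican, at 1.81-fold, and Igfbp2 at 1.42-fold, from 1113 ± 18 to 1589 ± 218. Several falls were in genes of calcium and lipid signalling: Itpka, which encodes an inositol trisphosphate kinase, fell 1.55-fold, Ptk2b, which encodes a calcium-responsive tyrosine kinase, 1.57-fold, the plasma membrane calcium pump gene Atp2b2 1.41-fold (3 of its 4 probe sets passing), and the cannabinoid receptor gene Cnr1 1.43-fold, from 1733 ± 166 to 1210 ± 70. The proteoglycan genes Cspg5, Sdc3 and Agrn fell 1.59-fold, 1.56-fold and 1.35-fold, Agrn on 1 of 2 probe sets. None of these themes was tested as a group, and the calls come from the model in which leaving out control 1 left 14 and leaving out control 2 left 11 calls.

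Of 7 changed probe sets without a gene symbol, 5 rose and 2 fell. The largest rise, in AF030088UTR#1_at, was 5.43-fold, from 74.8 ± 18.1 to 401 ± 30, and AF028784mRNA#1_s_at rose 3.23-fold, to 2679 on KCl 1 and 1467 on KCl 2. The largest fall, in rc_AI228669_at, was 2.46-fold, from 1002 ± 73 to 410 ± 65. Among the probe sets left out of the test, 4 had an adjusted p below 0.05 in a limma fit of all 1322 probe sets, all lower after KCl. They were 3 dim probe sets (Sele, Adora2b and Npy5r), within background on all arrays, and the hexokinase control probe set of the 5′ end, which read 479 and 561 in controls and 286 and 300 after KCl. That of the 3′ end was lower too, with 1080 and 1123 in controls and 711 and 802 after KCl, and did not pass (adjusted p = 0.059), while the groups overlapped for the middle one, with 1028 and 1557 against 1076 and 1098.

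The astrocyte markers rose on the KCl arrays while the neuron markers stayed near 0 in the mean. An array scaled too high would raise both lists alike, and the mean log2 change of the astrocyte markers exceeded that of the neuron markers by 1.106 ± 0.168. This error comes from the scatter between the genes of each list, not from limma's SEs. It takes genes as independent and does not measure how the difference varies between arrays. A larger share of astrocyte RNA as the only change would raise all markers by one factor, and the 5 above background in both groups scattered too much for this (Cochran's Q from limma's SEs was 30.46, against a 95% bound of 9.49, and 33.2 over all 7, bound 12.6). That scatter comes from Glul, which rose less than the others, so a larger astrocyte share together with a separate course of Glul, which other cells may also express, stays open and untested. A lower share of neuronal RNA cannot be told apart from this, since 2 of the 5 oligodendrocyte markers, with a mean log2 change of −0.06228, lay above background, and induction of these genes by KCl stays open and untested.

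Gad1 and Slc32a1 fell by 1.68 in the mean of their log2 changes. Their mean minus that of the neuron markers was −1.709 ± 0.116, an error from the scatter between genes and not from limma's SEs. Both were picked as the called falls of their list, where Abat and Slc6a11 had −0.15 and −0.01. A large difference was thus built in. A scale error would move all genes alike, and the neuron markers, with a mean of 0.03, showed no common shift of this size. A loss of GABAergic neurons of all kinds alike as the only change would lower their transcripts by one factor. The 8 above background in both groups (Gad1, Slc32a1, Sst, Nxph1, Npy, Pnoc, Tac1 and Htr3a) scattered more than this allows (Cochran's Q of 238.3, bound 14.1). The set was put together after the values were seen, from falls already called and genes already seen not to pass. A large Q was thus built in, and it carries no weight beyond the single values. Sst and Nxph1 fell about as far as Gad1 and Slc32a1, while Npy, Pnoc, Tac1 and Htr3a, with log2 changes of 0.23, 0.12, −0.18 and −0.45, did not pass, and the other probe set of Pnoc had −0.23. A loss limited to some of these neurons, a wider loss hidden in the 4 other genes by raised transcription or by other cells that make them, or lower transcription of the GABA genes may account for the fall, and none of these was tested.

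The 4 arrays can be split into 2 and 2 in 3 ways, too few for a share under 0.05. The real split gave 102 calls and 1 of the 3 splits gave as many, itself. The highest of the others gave 0 by limma, where 11 and 16 probe sets had an unadjusted p below 0.05. Each of these other splits puts 1 control and 1 KCl array in each group. Any difference between control and KCl then widens their variance, whatever its cause, so the 0 decides nothing.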
